A study of Rattus norvegicus albus with 14 samples.

How the data were processed

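RNA was sequenced from neonatal rat ventricular myocytes that had received 1% DMSO or 10 µmol/L rosiglitazone in 1% DMSO. Per the labels' protocols, total RNA was isolated with a spin-column kit and libraries were made with a directional kit that keeps strand information. The submitters' processing notes name FastQC 0.11.5, cutadapt 1.11, HTSeq and DESeq2, without giving the role or order of each. The same notes name the rat build Rnor_6.0 and the human build hg19. The aligner and the strand setting of the counting are not given in the sources used here. All gene IDs in the tables are rat Ensembl IDs (0 entries were not), although the series title speaks of mice.

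The deposited tables hold raw read counts per gene and sample, as whole numbers, together with results of the authors. Per the file headers, these results are a log2 fold change with its standard error and a p-value with its adjusted value, for 3 comparisons (rosiglitazone against DMSO at 0.5 h, 24 h against 0.5 h, and 48 h against 24 h). Each table lists 33005 entries for 32545 genes, because 460 entries repeat a gene for a second human homolog, and each gene was used once. For 24 genes no symbol is paired with the ID. The 4 libraries that occur in 2 tables had equal counts in both.

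The 14 samples are 7 libraries, each given as 2 splits. The splits of a library were compared by a chi-square test over genes with at least 20 summed counts, differed by about the sampling noise, and were summed. The groups are DMSO 0.5 h with 1 library and rosiglitazone 0.5, 24 and 48 h with 2 libraries each. Libraries held 10886559 to 28074620 counts. A count of 0 in a library allows up to 3 counts, which was 0.107 CPM in the deepest library and 0.276 CPM in the shallowest before scaling. Such limits cover counting error only, since reads without molecular identifiers are not independent molecules.

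Differential expression was tested with edgeR 4.0.16 in R 4.3.3, on the counts as deposited, with TMM scaling, the tool's own filter on low counts, robust quasi-likelihood dispersions and 4 groups in 1 fit. The fit covered 15655 genes with 3 residual degrees of freedom, a median of 4.46 prior degrees of freedom and a common biological coefficient of variation of 0.514. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. CPM values are counts relative to the library size after TMM scaling, and SD is the spread between 2 libraries. A gene with 0 counts in both libraries of a group has a fold change given as a bound against 3 counts in the shallowest library of that group, never as the fitted value.

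A total of 29 gene lists, written before the data were examined, covered metabolic pathways, heart muscle programs, stress and immune responses, the cell cycle, RNA classes and markers of other cell types that a heart culture can hold. Of 583 list entries, 567 were matched to a gene, 3 of them through a synonym, and every list had at least 5 measured members. Lists were tested with camera in limma 3.58.1, which compares the genes of a list with all other genes, at a preset correlation of 0.01, with a prior count of 2 for log2 CPM. The same test with a correlation estimated per list, and fry, which asks whether the genes of a list move on balance in 1 direction, were alternatives. The estimated correlation rests on 3 residual degrees of freedom, which leaves that test little power, so a list not called there is undecided. Adjusted p-values of lists are over the 29 lists of a comparison.

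The samples in each fit, the tests, the alternatives and the rule for naming genes were also fixed before the data were examined. The rule names, per comparison, up to 6 genes with the largest increase and 6 with the largest decrease among those past the threshold. These needed a mean of at least 5 CPM, an official symbol and no overlap between libraries of the groups. It adds up to 4 members with the smallest adjusted p from each list with a call or with at least 3 members past the threshold, and a fixed set of PPAR, lipid and cardiac genes. A comparison with no gene past the threshold names the 4 genes with the smallest p. List members with the larger adjusted p were left out where the rule named more than about 30 genes. The alternatives were DESeq2 size factors, DESeq2 1.42.0 as the test, no filter or a mean of at least 5 CPM, splits as separate replicates, each split alone, only the groups compared, the replicate number as a block, other thresholds, and leaving out each library in turn.

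The fit was tested on simulated counts for the same 15655 genes, with 200 genes changed per comparison, 50 at each of 4 sizes. At 2-fold, 4-fold, 8-fold and 16-fold it recovered 1, 13, 25 and 29 genes of 50 for rosiglitazone against DMSO at 0.5 h, with 14 false calls. For 24 h against 0.5 h it recovered 1, 25, 34 and 37, with 10 false calls. For 48 h against 24 h it recovered 2, 19, 31 and 33, with 15 false calls. For 48 h against 0.5 h it recovered 2, 24, 34 and 34, with 19 false calls. In each comparison the false calls were more than 5% of all calls of the simulated data, so the adjusted p of 0.05 did not hold there, and more than that share of the 15 and 1031 calls made here may be false. The simulated counts gave a gene the same spread in all groups, unlike the data, so recovery and false calls may differ in the data.

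Reads of near-identical copies can be placed on the wrong copy or left out in counting. Values of Acot1 and Acot2, Myh6 and Myh7, Mt1 and Mt2A, the globin genes and the histone genes are therefore uncertain to that extent. No genome or coordinates were used here.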

Results

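The series measured messenger RNA in neonatal rat ventricular myocytes, heart muscle cells taken from 1-day-old Sprague-Dawley rats and grown in culture, over a course of exposure to rosiglitazone. Rosiglitazone is a thiazolidinedione drug that activates the nuclear receptor PPARγ, a regulator of lipid genes. The data comprised 1 library of DMSO vehicle at 0.5 h and 2 libraries each of rosiglitazone at 0.5, 24 and 48 h. Each library had been deposited as 2 splits. The splits of a library differed by about the sampling noise (chi-square per degree of freedom 0.963 to 1.02, smallest p of the 7 pairs 0.112) and were counted as 1 sample. Libraries of 1 group differed by far more, with 26.4 at 0.5 h, 149 at 24 h and 63.0 at 48 h. Total counts were 28000661 for DMSO and 28074620 and 27360284 for rosiglitazone at 0.5 h. They were 24341710 and 25193522 at 24 h and 27467157 and 10886559 at 48 h, so that replicate 2 of 48 h was the shallowest. No vehicle library of 24 or 48 h was analysed here, so time in culture and time with the drug move together in every comparison between times. Nothing in the labels says that libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

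The libraries of 24 h stood further apart than those of the other times. Between replicates 1 and 2, 5640 genes differed by more than 2-fold at 24 h, against 2052 at 0.5 h and 3894 at 48 h. Sarcomere genes, which encode the contractile apparatus, held 1.49% of counts in replicate 1 of 24 h and 0.460% in replicate 2. Their share was 1.107% in DMSO, 1.90% and 1.83% in rosiglitazone at 0.5 h, and 0.0712% and 0.260% at 48 h. Genes of the mitochondrial genome held 2.96% and 0.737% of counts at 24 h, against 2.01% and 1.80% at 0.5 h and 0.831% and 0.562% at 48 h.

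**Figure D1:**
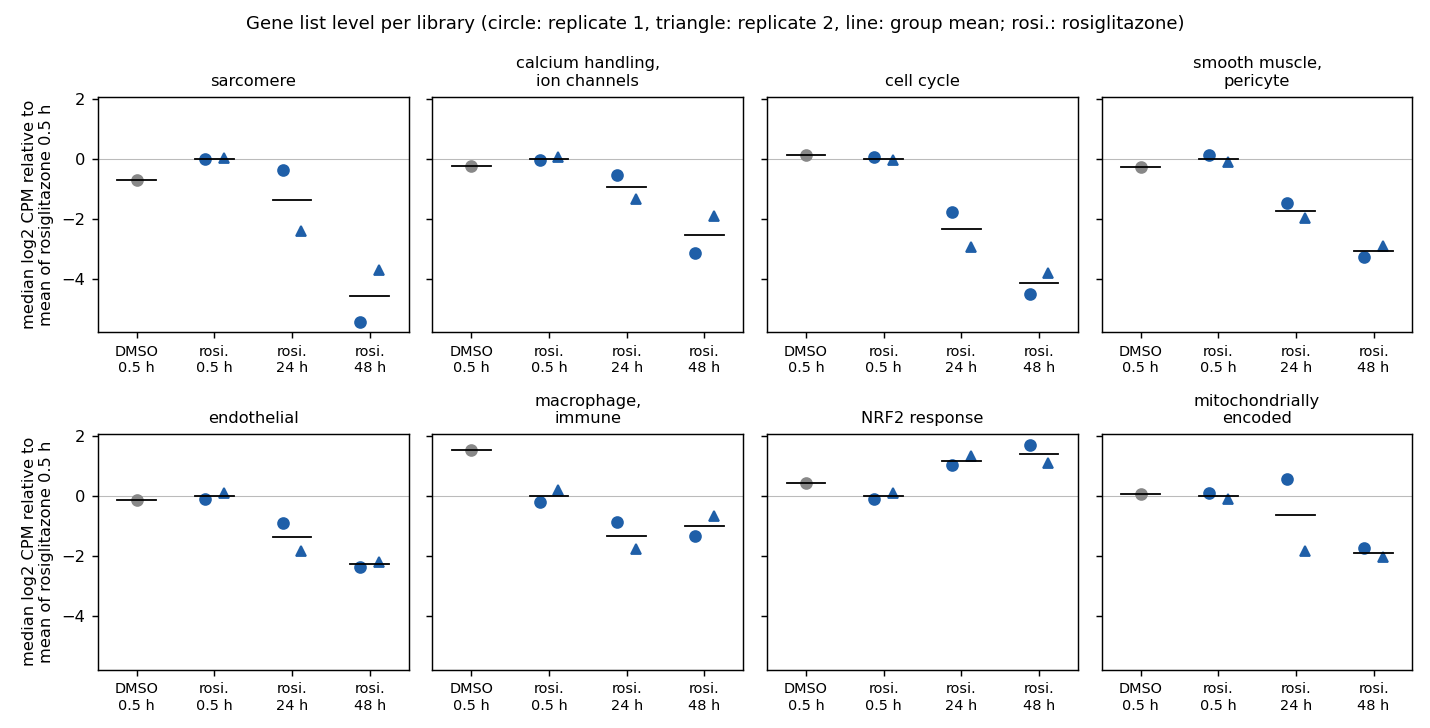
Median log2 CPM of 8 gene lists per library, relative to the mean of rosiglitazone at 0.5 h, for DMSO 0.5 h (grey, 1 library) and rosiglitazone 0.5, 24 and 48 h (blue, circle replicate 1, triangle replicate 2, line mean). Sarcomere genes lay at -0.38 and -2.40 at 24 h and at -5.43 and -3.72 at 48 h, and macrophage genes at 1.54 in DMSO.

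Rosiglitazone against DMSO at 0.5 h asks which genes differ after 0.5 h with the drug, and is the comparison with a vehicle library at the same time. With 1 DMSO library, it cannot tell a response from a difference between libraries. Transcripts of macrophage genes were less abundant in both rosiglitazone libraries than in DMSO. Csf1r, the receptor of macrophage colony-stimulating factor, was at 33.4 and 37.8 CPM against 109 in DMSO (log2 fold change -1.61 ± 0.41 SE). The mannose receptor Mrc1 was at 57.3 and 73.5 CPM against 189 (-1.53 ± 0.51), and the complement gene C1qc at 6.20 and 10.9 CPM against 31.4 (-1.88 ± 0.66). Single immediate early genes were more abundant in both, such as the mRNA-decay factor Zfp36 (151 and 125 CPM against 43.2, 1.68 ± 0.36) and the phosphatase Dusp1 (118 and 100 CPM against 43.8, 1.32 ± 0.35). None of these genes passed the threshold after adjustment. The fit shares its spread over all groups. Across genes, the log2 difference between replicates had an SD of 0.812 at 0.5 h, 1.60 at 24 h and 1.23 at 48 h. The shared spread is therefore wide for the libraries of 0.5 h, and few calls there do not show that few genes differed.

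By edgeR, 0 of 15655 genes passed at 0.5 h, the smallest adjusted p was 0.288, and 95 genes had an unadjusted p under 0.05, 17 higher and 78 lower. DESeq2 called 2 genes. The genes with the smallest p were LOC500035 (5.57 and 6.14 CPM against 81.1, log2 fold change -3.79 ± 0.40), AC128848.1 (-3.48 ± 0.60), the metallothionein Mt1 (-2.37 ± 0.47) and Creg1, a lysosomal glycoprotein (-1.80 ± 0.37). In the authors' deposited table for this comparison, 1677 genes had an adjusted p under 0.05, 771 higher and 906 lower, and 100% of those tested here had the same sign. Those results and the values here rest on the same counts, so the equal sign is no independent check in any comparison.

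Of the 29 lists at 0.5 h, 8 were called by camera at the preset correlation, 6 higher and 2 lower, and 0 with an estimated correlation or by fry. The DMSO arm is 1 library with its spread taken from the other groups, so a single deviating DMSO library could give the same calls. Of 15 macrophage genes, 0 had a positive fold change and the median was -1.53 (adjusted p = 2e-15, and adjusted p = 0.56 with an estimated correlation). Of 18 genes of the NRF2 response to oxidative stress, 2 had a positive fold change (median -0.44, adjusted p = 5.2e-08, and adjusted p = 0.56 with an estimated correlation). In that list 0 genes passed over all genes and 1, Mt1, was lower adjusted over the list alone. For every other list at 0.5 h, 0 members passed either over all genes or adjusted over the list alone. Hmox1, which degrades heme, was at 185 and 229 CPM against 425 (-1.04 ± 0.33). All 7 red blood cell genes had a positive fold change (median 1.33, adjusted p = 1.2e-05, and adjusted p = 0.56 with an estimated correlation), including the globin Hbb at 77.8 and 150 CPM against 44.4. The fetal and hypertrophy genes had a median of 0.62 (15 of 16 positive, adjusted p = 1.4e-05, and adjusted p = 0.70 with an estimated correlation), with the natriuretic peptide gene Nppa at 1657 and 1448 CPM against 856 (0.86 ± 0.59). The sarcomere genes had a median of 0.71 (20 of 21 positive, adjusted p = 0.00046, and adjusted p = 0.89 with an estimated correlation). Myh7, the slow myosin heavy chain, was at 2913 and 2373 CPM against 1307 (1.02 ± 1.19), and Myh6, the fast form, at 1212 and 1209 against 963. Of 28 immediate early genes, 19 had a positive fold change (median 0.16, adjusted p = 0.0008, and adjusted p = 0.61 with an estimated correlation), among them Fos (227 and 173 CPM against 78.8) and Egr1 (1011 and 629 against 488). Without rosiglitazone 0.5 h replicate 1 the number of called lists was 4, and the calls of the sarcomere (adjusted p = 0.072), fetal (0.13) and immediate early genes (0.19) and of p53 targets (0.13) were lost. The p53 targets had a median of 0.24 (14 of 16 positive, adjusted p = 0.022, and adjusted p = 0.61 with an estimated correlation), and subunits of oxidative phosphorylation also had 0.24 (25 of 25 positive, adjusted p = 0.017, and adjusted p = 0.89 with an estimated correlation). The sarcomere call was lost as well without rosiglitazone 0.5 h replicate 2 (adjusted p = 0.0565), as were those of p53 targets (0.155) and oxidative phosphorylation (0.773).

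Genes that PPAR factors are known to activate showed no common direction at 0.5 h. Of 33 measured, 13 had a positive fold change, and the median was -0.08 (camera adjusted p = 0.41). Angptl4, an inhibitor of lipoprotein lipase, was at 35.9 and 43.1 CPM against 95.7 in DMSO (log2 fold change -1.28 ± 0.34), and the fatty acid binding protein gene Fabp4 at 18.5 and 25.3 against 64.7 (-1.56 ± 0.80). Pdk4, which restrains glucose oxidation, was at 14.4 and 21.7 CPM against 10.4 (0.79 ± 0.51). Among the receptors, Pparg itself was at 1.44 and 2.47 CPM against 1.31, Ppara at 3.77 and 6.61 against 3.96, and Ppard at 35.0 and 30.7 against 35.5. The edgeR adjusted p of each of these 6 genes was 1.

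**Figure D2:**
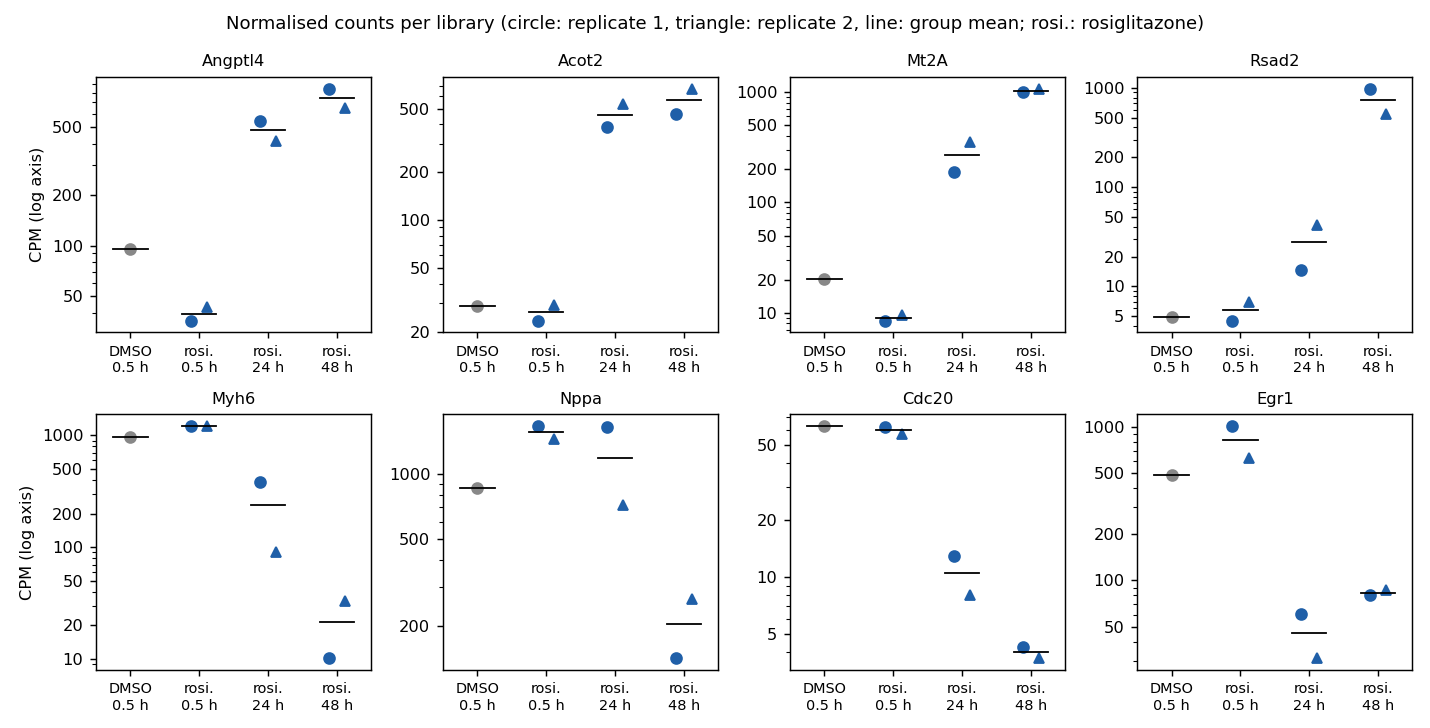
CPM on a log axis of 8 genes per library in DMSO 0.5 h (grey) and rosiglitazone 0.5, 24 and 48 h (blue, circle replicate 1, triangle replicate 2, line mean). Angptl4 lay at 95.7 in DMSO, at 35.9 and 43.1 in rosiglitazone at 0.5 h and at 545 and 417 at 24 h, and Myh6 at 10.2 and 33.0 at 48 h.

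The comparison of 24 h with 0.5 h of rosiglitazone asks what changed over the first day. Genes that rose included the PPAR targets Angptl4 and Acot2, the metallothioneins, Cyp1a1 and Pvalb. Angptl4 rose 12.2-fold, to 481 ± 90.4 CPM (SD, n = 2) from 39.5 ± 5.04, and Acot2, a mitochondrial acyl-CoA thioesterase, rose 17.3-fold, to 458 ± 107 from 26.4 ± 4.33 (edgeR adjusted p 0.019 for both). In DMSO at 0.5 h these genes were at 95.7 and 29.0 CPM. The metallothioneins Mt1 and Mt2A, which bind zinc and copper, rose by log2 fold changes of 6.70 ± 0.47 and 4.91 ± 0.40, and the cytochrome P450 gene Cyp1a1 rose 71.0-fold, to 70.5 ± 21.6 CPM from 0.989 ± 0.452. The immediate early gene Egr1 fell 18.0-fold, to 45.7 ± 20.4 CPM from 820 ± 270, and the matricellular gene Cyr61 fell 18.4-fold. Egr1, like Fos and Dusp1, was higher in rosiglitazone than in DMSO at 0.5 h, so its fall from that DMSO level was smaller.

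By edgeR, 15 genes passed at 24 h, 8 higher and 7 lower, and 2454 had an unadjusted p under 0.05, 1026 higher and 1428 lower. Besides those above, the calcium buffer gene Pvalb rose by a log2 fold change of 5.32 ± 0.51 (adjusted p = 0.020). Itga11, a collagen-binding integrin, fell by 4.89 ± 0.47 (adjusted p = 0.020), the basement membrane collagen Col4a4 fell by 2.52 ± 0.28 (0.036), Dusp1 fell by 2.57 ± 0.29 (0.036), Crim1 fell by 2.38 ± 0.27 (0.038) and Ier2 fell by 2.30 ± 0.28 (0.047). All 15 genes were also called by DESeq2, which called 416 higher and 843 lower, 1259 in all. Leaving out either library of 24 h raised the number of calls, which still included these genes. That step leaves 1 library at 24 h and takes the difference between the libraries of 24 h, wider than at 0.5 or 48 h, out of the spread. It is therefore no further support for these genes. Without either rosiglitazone library of 0.5 h or either library of 48 h, 0 genes passed, without DMSO 10 did (8 higher and 2 lower), and with only the 2 groups in the fit 0 did. The authors' deposited table lists 6239 genes for this comparison, 2849 higher and 3390 lower, and 100% of those tested here had the same sign. With each split as its own replicate, edgeR called 5629 genes, though splits of a library are not independent. Whether this accounts for the authors' number was not tested.

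Of the 29 lists, 20 were called at 24 h at the preset correlation, 0 with an estimated correlation and 4 by fry. Those by fry were the immediate early, NRF2 and unfolded protein lists (fry adjusted p = 0.040 for each) and the histones (0.010). Fry did not call the cell cycle (0.062), PPAR target (0.17) or fatty acid oxidation lists (0.29). Of the 20 calls at the preset correlation, 9 were higher and 11 lower. This balance turned with the library left out, with 5 higher and 15 lower without rosiglitazone 24 h replicate 1, and 11 higher and 6 lower without rosiglitazone 24 h replicate 2. The cell cycle genes had the smallest p among lists with a lower level. Of 29, 0 passed over all genes, 23 were lower adjusted over the list alone, and the median was -2.45 (adjusted p = 4.7e-13, and adjusted p = 0.46 with an estimated correlation). Cdc20, an activator of the anaphase-promoting complex, was at 10.5 ± 3.38 CPM against 59.9 ± 3.76 (adjusted p = 0.068), the checkpoint kinase gene Bub1 at 11.2 ± 3.63 against 67.7 ± 13.2 (0.068), and Plk1 at 4.33 ± 0.749 against 39.8 ± 0.347 (0.071). Of 28 immediate early genes, 3 fell (Egr1, Dusp1 and Ier2), 12 were lower and 1 higher adjusted over the list alone, and the median was -1.06 (adjusted p = 1.1e-05, and adjusted p = 0.46 with an estimated correlation). Fos was at 5.48 ± 1.03 CPM against 200 ± 38.0 (adjusted p = 0.066).

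Among the lists with a higher level at 24 h, 2 of 18 NRF2 genes rose over all genes (Mt1 and Mt2A, which metals also induce), and 13 were higher adjusted over the list alone. Their median was 1.33 (adjusted p = 9.4e-12, and adjusted p = 0.45 with an estimated correlation). The quinone reductase gene Nqo1 was at 679 ± 5.43 CPM against 124 ± 14.6 (adjusted p = 0.061), with 186 in DMSO. The PPAR target list had 2 genes that rose over all genes, Angptl4 and Acot2, and 6 adjusted over the list alone (median 0.62, adjusted p = 7.3e-05, and adjusted p = 0.46 with an estimated correlation). Of 19 fatty acid oxidation enzymes, 0 passed over all genes and 8 were higher adjusted over the list alone (median 0.93, adjusted p = 1.5e-05, and adjusted p = 0.46 with an estimated correlation). Hadhb was at 1493 ± 233 CPM against 487 ± 62.5 (adjusted p = 0.085). The call of this list was lost without rosiglitazone 24 h replicate 1 (adjusted p = 0.084). Of 24 genes of the unfolded protein and integrated stress response, 0 passed over all genes and 11 were higher adjusted over the list alone (median 0.66, adjusted p = 1.1e-05, and adjusted p = 0.45 with an estimated correlation), with the chaperone gene Dnajb9 at 310 ± 64.4 CPM against 69.7 ± 7.78 (adjusted p = 0.061). Other fixed genes did not pass: Pdk4 was at 21.9 and 38.8 CPM against 14.4 and 21.7 (adjusted p = 0.41), Plin2, which coats lipid droplets, at 273 and 223 against 194 and 209 (0.70), Cpt1a at 159 ± 25.3 against 160 ± 11.1 (1), Fabp4 at 23.7 ± 18.3 against 21.9 ± 4.81 (0.96), and Pparg at 4.13 ± 1.26 against 1.96 ± 0.726 (0.56).

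Heart muscle genes and the markers of 4 other cell types were lower at 24 h at the preset correlation, and 0 members of any of these lists except Cyr61 in the fetal list passed over all genes. The median was -1.06 for sarcomere genes (4 of 21 lower adjusted over the list alone, adjusted p = 0.0016, and adjusted p = 0.58 with an estimated correlation). It was -1.46 for the fetal program (5 of 16 lower and 1 higher, Gdf15, adjusted over the list alone, adjusted p = 0.00077) and -0.71 for calcium handling (1 of 23, Ryr2, adjusted p = 0.0058), each with adjusted p = 0.46 with an estimated correlation. Among other cell types it was -1.96 for smooth muscle (5 of 14, adjusted p = 6.1e-05), -1.09 for endothelium (6 of 11, adjusted p = 0.00058), -1.20 for macrophages (3 of 15, adjusted p = 0.0024), -1.25 for epicardium (4 of 12, adjusted p = 0.00028) and -0.82 for extracellular matrix (7 of 27, adjusted p = 0.00042). The counts are of members lower adjusted over the list alone, and the adjusted p was 0.46 with an estimated correlation for each. Fibroblast markers were not called (median -0.70, 0 of 15 over all genes or adjusted over the list alone, adjusted p = 0.12), nor were glial (0.45) or red blood cell markers (0.052). The ryanodine receptor gene Ryr2 was at 69.6 ± 9.12 CPM against 366 ± 62.1 (edgeR adjusted p = 0.081), and Ppargc1a, a coactivator that drives mitochondrial genes, at 3.25 ± 1.40 against 17.6 ± 4.36 (0.11). Myh6 was at 385 and 90.5 CPM in the libraries of 24 h (adjusted p = 0.20) and Nppa at 1640 and 720 (0.71). Without rosiglitazone 24 h replicate 2, the calls of sarcomere (adjusted p = 0.57), calcium handling (0.18), endothelial (0.054) and macrophage genes (0.39) were lost. Without rosiglitazone 0.5 h replicate 2, that of calcium handling was lost (adjusted p = 0.057).

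The comparison of 48 h with 24 h asks what changed over the second day. Transcripts of 2 chemokines and of 1 antiviral gene were among those more abundant at 48 h. Cxcl10, a chemokine that attracts T cells, was at 151 ± 54.9 CPM (SD, n = 2) against 10.1 ± 0.949 at 24 h, and 6.01 in DMSO at 0.5 h. The chemokine Ccl6 was at 130 ± 47.7 CPM against 6.91 ± 2.84, and Rsad2, an antiviral enzyme, at 765 ± 307 against 28.0 ± 18.8. All 21 sarcomere genes had a negative fold change, such as the troponin gene Tnnc1 at 45.3 ± 36.4 CPM against 988 ± 877 and Myh6 at 21.6 ± 16.1 against 238 ± 209. No gene passed the threshold after adjustment.

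By edgeR, 0 genes passed for 48 h against 24 h, the smallest adjusted p was 0.161, and 1274 had an unadjusted p under 0.05, 438 higher and 836 lower. DESeq2 called 511 genes, and leaving out replicate 2 of 24 h gave 509 and leaving out replicate 2 of 48 h gave 1. The genes with the smallest p were Cxcl10 (log2 fold change 3.90 ± 0.38), Ccl6 (4.24 ± 0.46), the collagen Col8a1 (-2.71 ± 0.32) and Fam111a (-4.04 ± 0.49), each with adjusted p = 0.16. The authors' deposited table lists 2452 genes, 1042 higher and 1410 lower, and 100% of those tested here had the same sign. With each split as its own replicate, edgeR called 2890 genes, and whether this accounts for the authors' number was not tested.

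Of the 29 lists, 16 were called for 48 h against 24 h at the preset correlation, 3 higher and 13 lower, and 0 with an estimated correlation or by fry. Without rosiglitazone 24 h replicate 1 there were 9. In every list, 0 members passed over all genes. Sarcomere genes had the lowest median of the called lists, at -2.99, and 20 of 21 were lower adjusted over the list alone (adjusted p = 2.8e-17, and adjusted p = 0.48 with an estimated correlation). Calcium handling genes had a median of -1.49 (7 of 23 lower adjusted over the list alone, adjusted p = 1.1e-09) and the fetal program -1.56 (9 of 16, adjusted p = 1.4e-07), both with adjusted p = 0.48 with an estimated correlation. Casq2, which stores calcium in the sarcoplasmic reticulum, was at 11.9 ± 6.61 CPM against 157 ± 141, and Nppa at 203 ± 87.2 against 1180 ± 651 (edgeR adjusted p = 0.28 for both). Cell cycle genes had a median of -1.77 (17 of 29 lower adjusted over the list alone, adjusted p = 3.3e-13, and adjusted p = 0.48 with an estimated correlation), with the survivin gene Birc5 at 0.462 ± 0.136 CPM against 7.18 ± 3.44 (edgeR adjusted p = 0.27). Genes of the mitochondrial genome were lower as well (median -1.50, 0 of 11 positive, 0 adjusted over the list alone, adjusted p = 0.0011, and adjusted p = 0.58 with an estimated correlation), a call lost without rosiglitazone 24 h replicate 1 (adjusted p = 0.975) and without rosiglitazone 48 h replicate 2 (0.108). Smooth muscle markers had a median of -1.45 (0 of 14 adjusted over the list alone, adjusted p = 4.5e-05, and adjusted p = 0.48 with an estimated correlation), a call lost without rosiglitazone 48 h replicate 1 (adjusted p = 0.085).

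Inflammatory cytokines had a median of 1.47 from 24 to 48 h (11 of 18 higher adjusted over the list alone, adjusted p = 3.6e-11, and adjusted p = 0.48 with an estimated correlation). Immediate early genes had a median of 0.55 (4 of 28 higher and 1 lower adjusted over the list alone, adjusted p = 3.6e-06, and adjusted p = 0.48 with an estimated correlation). The interferon list moved both ways. Adjusted over the list alone, 4 of 20 were higher, including Ifit3 (3.66 ± 0.45) and Rsad2 (4.77 ± 0.61), and 7 were lower, including Irf7 (-2.38 ± 0.40) and Mx2 (-2.94 ± 0.64). Its median was -0.70 (adjusted p = 0.033, and adjusted p = 0.58 with an estimated correlation), and the call was lost without rosiglitazone 24 h replicate 1 (adjusted p = 0.11), without rosiglitazone 24 h replicate 2 (0.29) and without rosiglitazone 48 h replicate 1 (0.075). PPAR targets had a median of -0.74 (0 of 33 adjusted over the list alone, adjusted p = 0.0056, and adjusted p = 0.58 with an estimated correlation). That call was lost without rosiglitazone 24 h replicate 1 (adjusted p = 0.17) and without rosiglitazone 48 h replicate 1 (0.45). In this list Acsl1, which activates long-chain fatty acids, was at 96.5 ± 41.7 CPM against 422 ± 197 (edgeR adjusted p = 0.28). Angptl4 was at 745 ± 139 CPM against 481 ± 90.4 (0.66), Plin2 at 402 ± 167 against 248 ± 35.5 (0.68) and Pdk4 at 27.2 and 26.4 against 21.9 and 38.8 (0.98).

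The comparison of 48 h with 0.5 h of rosiglitazone spans the whole course. Of the heart muscle and cell division genes, 15 of 21 sarcomere and 21 of 29 cell cycle genes fell. The metallothioneins, 4 of 20 interferon response genes and 5 of 33 PPAR targets rose. In the interferon list 1 gene fell, and the interferon and PPAR lists were not called as a whole. Myh6 fell 56.4-fold, to 21.6 ± 16.1 CPM (SD, n = 2) from 1210 ± 2.41 (edgeR adjusted p = 0.016), with 963 in DMSO, and the ryanodine receptor Ryr2 fell 22.0-fold, to 16.7 ± 9.60 from 366 ± 62.1 (0.0072). Mt1 rose 329-fold, to 213 ± 39.5 CPM from 0.644 ± 0.0364 (0.0044), and Rsad2 rose 133-fold, to 765 ± 307 from 5.72 ± 1.72 (0.0065). Angptl4 rose 18.9-fold and Acot2 21.4-fold (0.0050 for both). Mt1 and Angptl4 were lower in rosiglitazone than in DMSO at 0.5 h, so their rise over that DMSO level was smaller. Myh6, Myh7, Nppa, Fos and Egr1 were higher in rosiglitazone than in DMSO at 0.5 h, so their fall from that DMSO level was smaller. The cell division gene Cdc20 fell 14.9-fold, to 4.28 and 3.72 CPM from 62.5 and 57.2 (0.0065).

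By edgeR, 1031 genes passed for 48 h against 0.5 h, 308 higher and 723 lower, and 3592 had an unadjusted p under 0.05. DESeq2 called 2582, which included all 1031. Of the 1031 genes, 11 were still called without replicate 1 of 48 h (12 calls in all, 11 higher and 1 lower), 305 without replicate 2 of 48 h (397 calls), 35 without replicate 1 of rosiglitazone 0.5 h (35 calls) and 95 without replicate 2 (95 calls). Leaving out replicate 1 or 2 of 24 h raised the number of calls, where the difference between these libraries no longer enters the spread. With the largest increases stood also Pvalb (log2 fold change 7.75 ± 0.56), the immune receptor Slamf7 (7.77 ± 1.52), Vat1l (7.45 ± 0.79) and Star, which carries cholesterol into mitochondria for steroid synthesis (7.26 ± 0.89). Slamf7 was at 43.7 and 5.02 CPM at 48 h against 0.211 and 0, and Star at 398 ± 87.5 against 2.60 ± 1.01. Among the genes named here that fell, 4 were at 0 counts in both libraries of 48 h, so that their decrease is known only as a bound and cannot be ranked. Against 3 counts in the shallower of these, the heart-specific kinase gene Tnni3k (28.4 ± 1.59 CPM at 0.5 h) was at least 102-fold lower, Dhrs9 at least 68.6-fold, Ns5atp9 at least 47.0-fold and Carns1 at least 42.3-fold lower. Of the genes named here with counts at 48 h, Lims2 fell by 8.08 ± 0.86 and Itgbl1 fell by 7.79 ± 1.05 on the log2 scale.

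Of the 29 lists, 16 were called for 48 h against 0.5 h at the preset correlation, 6 higher and 10 lower, 0 with an estimated correlation and 14 by fry. The calls by fry included the glial, red blood cell and histone lists, which camera did not call. Fry did not call the inflammatory (fry adjusted p = 0.11), macrophage (0.14), hypoxia, mitochondrial and ribosomal lists (0.21 for each), which camera called. Of 21 sarcomere genes, 15 fell over all genes and 20 adjusted over the list alone, with a median of -4.35 (adjusted p = 6.6e-12, and adjusted p = 0.37 with an estimated correlation). Myom2, which crosslinks myosin filaments, fell 93.4-fold, to 2.33 ± 1.70 CPM from 207 ± 7.01 (edgeR adjusted p = 0.016). Myh7 fell 55.0-fold by the fit (0.031), to 13.2 and 83.3 CPM in replicates 1 and 2 from 2643 ± 382. Without rosiglitazone 48 h replicate 1, without rosiglitazone 0.5 h replicate 1 and without rosiglitazone 0.5 h replicate 2, 0 sarcomere genes passed, and without rosiglitazone 48 h replicate 2, 5 did. Of 23 calcium handling genes, 9 fell over all genes and 15 adjusted over the list alone (median -2.42, adjusted p = 1.3e-07, and adjusted p = 0.37 with an estimated correlation), including Casq2 (43.0-fold, to 7.21 and 16.6 CPM from 506 ± 37.2). Without rosiglitazone 48 h replicate 1, 0 of them passed, without rosiglitazone 48 h replicate 2, 3, and without either rosiglitazone library of 0.5 h, 1. Of 16 fetal program genes, 9 fell over all genes and 13 adjusted over the list alone, and 1, Gdf15, rose in both counts (median -3.26, adjusted p = 2.4e-07, and adjusted p = 0.37 with an estimated correlation). Of the fetal program genes, 0 passed without rosiglitazone 48 h replicate 1, while 5 fell and 0 rose without rosiglitazone 48 h replicate 2, and without replicate 1 or 2 of rosiglitazone 0.5 h, 1 and 4 fell and 0 rose. Nppa fell 7.64-fold (0.020) and Nppb was at 9.30 ± 10.3 CPM against 322 ± 90.5 (0.051). Ppargc1a fell 9.34-fold, to 1.88 ± 0.0308 CPM from 17.6 ± 4.36 (0.022).

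Cell cycle genes and the markers of 4 other cell types were lower over the same span. Of 29 cell cycle genes, 21 fell over all genes and 27 adjusted over the list alone (median -3.94, adjusted p = 1.1e-16, and adjusted p = 0.37 with an estimated correlation), among them the cyclin gene Ccna2 (48.0-fold, edgeR adjusted p = 0.0072). Of these cell cycle genes, 0 passed without rosiglitazone 48 h replicate 1, 4 without rosiglitazone 0.5 h replicate 1 and 10 without rosiglitazone 0.5 h replicate 2. Smooth muscle markers had a median of -3.17, with 6 of 14 lower over all genes and 11 adjusted over the list alone (adjusted p = 2.4e-07). For endothelial markers these values were -1.97, 4 of 11 and 7 (4.7e-05), and for epicardial markers -1.64, 4 of 12 and 6 (0.00034). For these lists the adjusted p was 0.37 with an estimated correlation. In the smooth muscle, endothelial, epicardial, macrophage and extracellular matrix lists, 0 members passed without rosiglitazone 48 h replicate 1. In the same order, 3, 0, 2, 1 and 9 were lower without rosiglitazone 48 h replicate 2, 0, 0, 0, 0 and 1 without rosiglitazone 0.5 h replicate 1, and 2, 0, 0, 0 and 1 without rosiglitazone 0.5 h replicate 2. Macrophage markers had a median of -1.14, with 4 of 15 lower over all genes and 6 adjusted over the list alone (adjusted p = 0.013, and adjusted p = 0.57 with an estimated correlation), a call lost without rosiglitazone 0.5 h replicate 2 (adjusted p = 0.077). The endothelial receptor gene Kdr fell 12.9-fold (0.016), the smooth muscle gene Smtn 8.25-fold (0.014), the mesothelial gene Lrrn4 101-fold (0.014) and C1qc 26.6-fold (0.016). Of 27 extracellular matrix genes, 8 fell over all genes and 12 adjusted over the list alone, and 1 and 2 rose (median -1.28, adjusted p = 0.00034, and adjusted p = 0.37 with an estimated correlation). Fibroblast markers were not called by camera (median -1.28, adjusted p = 0.10), with 1 of 15 higher and 1 lower over all genes, and 2 higher and 5 lower adjusted over the list alone. Glial and red blood cell markers were not called by camera either (adjusted p = 0.11 for both) but were called lower by fry (0.031 and 0.047), with 1 of 11 and 0 of 7 lower over all genes, and 2 and 0 adjusted over the list alone. Col8a1 fell 27.2-fold, to 11.5 ± 0.730 CPM from 313 ± 43.1 (0.0049).

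Among the lists with a higher level at 48 h, 6 of 18 NRF2 genes rose over all genes and 14 adjusted over the list alone (median 1.35, adjusted p = 3.7e-10, and adjusted p = 0.37 with an estimated correlation), including Nqo1 (6.08-fold, edgeR adjusted p = 0.011) and the mitochondrial superoxide dismutase Sod2 (9.52-fold, 0.013). Without rosiglitazone 48 h replicate 1, 2 of them passed, as without rosiglitazone 0.5 h replicate 1 or without rosiglitazone 0.5 h replicate 2, while without rosiglitazone 24 h replicate 1, 13 did. Of 24 stress response genes, 5 rose over all genes and 8 adjusted over the list alone (median 0.61, adjusted p = 3.8e-05, and adjusted p = 0.37 with an estimated correlation), including Trib3, an inhibitor of AKT signalling (5.96-fold, 0.015). Of 18 inflammatory genes, 2 rose over all genes, Cxcl10 (28.2-fold, 0.0050) and Cxcl1, and 6 adjusted over the list alone (median 1.40, adjusted p = 0.00027, and adjusted p = 0.37 with an estimated correlation). Of 16 p53 targets, 2 rose over all genes, the growth arrest genes Gadd45a (6.65-fold, 0.012) and Cdkn1a (3.10-fold, 0.016). Adjusted over the list alone 4 rose and 1 fell (median 0.53, adjusted p = 0.011, and adjusted p = 0.37 with an estimated correlation). The interferon list was not called (adjusted p = 0.99, median -0.63, mean 0.18). Within it Rsad2, Ifit3 (30.3-fold, 0.0065), Isg15 (9.47-fold, 0.010) and Oasl (9.65-fold, 0.011) rose and Mx2 fell over all genes, and 4 rose and 4 fell adjusted over the list alone.

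The PPAR target list was not called at 48 h against 0.5 h (adjusted p = 0.24). Its median was -0.12, while its mean of 0.23 and the direction of its test were positive. Of 33 members, 5 rose both over all genes and adjusted over the list alone, namely Angptl4, Acot2, Acot1, Hadha and Klf15, and 0 fell. Without rosiglitazone 48 h replicate 1 the list was called (adjusted p = 0.015). Other lipid genes did not pass by edgeR: Plin2 was at 520 and 284 CPM against 194 and 209 (adjusted p = 0.13), Pdk4 at 26.8 ± 0.582 against 18.1 ± 5.15 (0.45), Cd36, a fatty acid transporter, at 85.1 ± 53.9 against 138 ± 32.7 (0.47), Fabp4 at 16.1 ± 11.8 against 21.9 ± 4.81 (0.75) and Cpt1a at 144 ± 44.8 against 160 ± 11.1 (0.81). Of the receptors, Pparg was at 2.00 ± 0.590 CPM against 1.96 ± 0.726 (1), Ppara at 5.75 ± 0.508 against 5.19 ± 2.01 (0.94) and Ppard at 46.5 ± 8.35 against 32.9 ± 3.02 (0.35). Of the 8 fallers among 28 immediate early genes, Fos fell 23.7-fold (0.016) and Egr1 9.82-fold (0.012), 1 gene, Dusp2, rose, and 11 fell and 3 rose adjusted over the list alone. That list was not called (median -0.20, adjusted p = 0.14).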

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

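The alternatives below were chosen before the data were examined. Counts of genes are given in the order rosiglitazone against DMSO at 0.5 h, 24 h against 0.5 h, 48 h against 24 h, and 48 h against 0.5 h, where edgeR called 0, 15, 0 and 1031. DESeq2 called 2, 1259, 511 and 2582. Without a filter on low counts there were 1, 334, 19 and 1265 calls, where the number of genes tested also changes. With each split as its own replicate there were 78, 5629, 2890 and 6943, where by construction each library counts as 2 samples that are not independent. With only the groups compared in the fit there were 174, 0, 0 and 2733. At an adjusted p under 0.01 there were 0, 0, 0 and 53. The counts ranged over the left-out libraries from 0 to 0, 0 to 1008, 0 to 509 and 12 to 2706, where a group left with 1 library is assumed to vary like the others. DESeq2 size factors (0, 16, 0 and 999), a mean of at least 5 CPM (0, 15, 0 and 1084) and a single split stayed within 1.5 times of each count. Except where construction is named, the cause was not tested. Called lists numbered 8, 20, 16 and 16. With an estimated correlation they numbered 0 in each comparison, and with fry 0, 4, 0 and 14. The estimated correlation hardly separated lists. At 48 h against 0.5 h, cell cycle genes and glial markers both had a camera adjusted p of 0.37 there, against 1.1e-16 and 0.11 at the preset correlation. Leaving out 1 library gave 4 to 8, 16 to 20, 9 to 17 and 14 to 19. Same-numbered libraries did not deviate together (correlations across genes of -0.08, 0.06 and -0.12 between times). These values cannot tell whether libraries with the same replicate number shared a preparation, which the labels do not give. The fit with that number as a block, which leaves 2 residual degrees of freedom, called 0, 1, 0 and 407 genes and 12, 20, 16 and 16 lists. The 332 values for genes chosen by the rule had 3594 alternative values. Of these, 2868 kept their side of the threshold, 314 lost a call, 412 gained one and 0 were counted as reversed. Genes without a call could change direction and still be counted as kept. The DESeq2 size factors moved the median gene by at most -0.02 on the log2 scale. Replicate 2 of 48 h, at 10886559 counts, sets the lowest level that can be seen at 48 h.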

Other observations

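The tests of explanations below were all chosen after the results were seen, and the gene lists before the data were examined. All 26 cytosolic ribosomal protein genes had a positive fold change from 0.5 to 24 h of rosiglitazone, with a median of 0.80 (camera adjusted p = 9.5e-06, and adjusted p = 0.46 with an estimated correlation), and 0 passed over all genes or adjusted over the list alone. That call was lost without rosiglitazone 24 h replicate 1 (adjusted p = 0.11). From 0.5 to 48 h, 25 of 26 were positive, the median was 0.86 (adjusted p = 4.6e-06, and adjusted p = 0.57 with an estimated correlation), and 0 rose over all genes and 6 adjusted over the list alone. Rpl18 was at 1479 ± 399 CPM (SD, n = 2) at 48 h against 607 ± 115 at 0.5 h. Of 11 genes of the mitochondrial genome, all were lower at 48 h than at 0.5 h (median -1.91, adjusted p = 0.0015, and adjusted p = 0.57 with an estimated correlation), with 0 past the threshold over all genes and 6 adjusted over the list alone. Mt-nd4l, a subunit of respiratory complex I, was at 16.5 ± 8.37 CPM against 77.3 ± 25.1 (edgeR adjusted p = 0.0504).

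Other metabolic lists differed between the libraries of 24 h. From 24 to 48 h the median was -0.66 for subunits of oxidative phosphorylation (0 of 25 positive, adjusted p = 1.7e-05), -0.61 for fatty acid oxidation (0 of 19 positive, adjusted p = 4.5e-05) and -0.72 for cholesterol synthesis (1 of 22 positive, adjusted p = 0.00052), each with adjusted p = 0.58 with an estimated correlation. None of these was called without rosiglitazone 24 h replicate 1, where the adjusted p was 0.700, 0.629 and 0.975. Hypoxia genes had a median of 0.24 from 0.5 to 48 h (adjusted p = 0.049, and adjusted p = 0.57 with an estimated correlation). In that list 3 of 16 genes rose over all genes, and 6 rose and 1 fell adjusted over the list alone. The list's call was lost without DMSO 0.5 h replicate 1 (0.057) and without each other library except replicate 2 of 48 h, such as without rosiglitazone 48 h replicate 1 (0.16). The glucose transporter gene Slc2a1 (5.95-fold, edgeR adjusted p = 0.011) and the hexokinase gene Hk2 (4.34-fold, 0.016), which the hypoxia and glycolysis lists share, rose over all genes. From 0.5 to 24 h the interferon genes had a median of 0.50 (adjusted p = 0.0015), with 0 of 20 past the threshold over all genes and 4 higher adjusted over the list alone, and adjusted p = 0.46 with an estimated correlation. Replication-dependent histone genes were called lower by camera at 24 h against 0.5 h (median -0.42, adjusted p = 0.048, and adjusted p = 0.46 with an estimated correlation) and by fry (0.010), with 0 of 10 past the threshold over all genes or adjusted over the list alone. The camera call was lost without each library except DMSO and replicate 1 of rosiglitazone 0.5 h, such as without rosiglitazone 24 h replicate 2 (adjusted p = 0.160). The histone genes were not called by camera at 48 h against 0.5 h (adjusted p = 0.10) but were called lower by fry (0.0027), with 0 of 10 past the threshold over all genes or adjusted over the list alone. The glial, red blood cell and histone lists had medians of -0.70, -0.37 and -0.28 when members at 0 counts are set at their bound.

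The authors' deposited table for rosiglitazone against DMSO at 0.5 h lists 1677 genes, and edgeR called 0 here, with 95 at an unadjusted p under 0.05. A choice of DESeq2 alone is argued against, since DESeq2 on the summed libraries called 2 genes. A candidate explanation is that splits of a library entered as replicates: DESeq2 then called 1753 genes between rosiglitazone and DMSO, within 1.5 times of the authors' count, in a fit of these groups alone, and 76 in the same fit with each library summed. The splits alone do not give that number, since edgeR with splits as replicates and all 4 groups in the fit called 78. In a fit of these groups alone, edgeR with splits as replicates called 1506. A response to rosiglitazone stays open: single rosiglitazone libraries differed from DMSO in 5313 and 6251 genes and from each other in 6360 when splits were the replicates, and 1 control library cannot tell a response from the difference between libraries.

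The libraries of rosiglitazone 24 h differed more than those of the other times, with sarcomere genes at a median of 2.13 and mitochondrial genes at 2.52 higher (log2) in replicate 1. A wrong label on a library of 0.5 h is argued against, since the highest correlation of replicate 1 with a library of 0.5 h was 0.919, below the lowest among libraries of 0.5 h, 0.963. The 0.919 was above the correlation of replicate 1 with replicate 2 of 24 h, 0.901. Replicate 1 correlated at 0.900 and 0.914 with the libraries of 48 h, and replicate 2 of 24 h at 0.928 and 0.924. A larger share of cardiomyocytes in replicate 1 would lower every other cell type there, but 5 of 5 marker lists of other types had their lower quartile above 0 in replicate 1. By summed share of counts, however, fibroblast markers held 3.32% in replicate 1 and 3.47% in replicate 2. The shares of smooth muscle, endothelial, macrophage and epicardial markers were higher in replicate 1. That replicate 2 may lie further along the change from 0.5 to 48 h stays open: across 15655 genes, which are not independent, its difference from replicate 1 had a Pearson correlation of 0.228 and a Spearman correlation of 0.19 with that change. No difference in treatment between these libraries is given in the labels, so no biological explanation from the design was tested.

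Sarcomere genes lay at a median of -4.35 (log2) at 48 h against 0.5 h. Fewer counts in replicate 2 of 48 h are argued against as the cause, since the median was -5.43 in replicate 1, which had 27467157 counts. A smaller share of cardiomyocytes among otherwise unchanged cells would raise the markers of other types, but 4 of 5 such lists (fibroblast, endothelial, smooth muscle and epicardial) had their upper quartile below 0, and macrophage markers had theirs at 0.07. Exposure to rosiglitazone and time in culture cannot be told apart, because 0 vehicle libraries of 48 h were analysed. The hypothesis that the drug lowers sarcomere transcripts therefore stays untested.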
